A study of Homo sapiens with 5 samples.

How the data were processed

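The data were 4 deposited peak lists from A549 cells: FOXM1 immunoprecipitation, LC3 immunoprecipitation, DNA of extracellular vesicles from untreated cells, and DNA of vesicles from cells kept 3 days in EBSS. Per the labels' protocols, cells for immunoprecipitation grew with 10% fetal bovine serum and were crosslinked in 1% formaldehyde over 10 minutes, cells for vesicle collection grew without serum, and reads were 50 bp single-end or 150 bp paired-end; which library had which is not given in the sources used here. An input library has a label but was not analysed here. Groups were taken from the antibody and treatment labels, with 1 library each, so there was no replicate to measure spread.

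Per the submitters' processing notes, the tools were fastp 0.20.0, FastQC 0.11.8, BWA, MACS3 3.0.0a6 and ChIPseeker, with the genome build hg38. Per the file headers and values, each list is a narrow peak list called per library and annotated with the nearest gene. The authors deposited for each peak a fold over the local background, a linear ratio. The lists also hold the authors' −log10 p-value and −log10 q-value for each peak. In the EBSS evDNA list the headings of these 2 columns are damaged, and the columns were identified by their position and by the Poisson recovery below. The numbering of peaks skips 81 numbers in FOXM1, 33 in LC3, 270 in control evDNA and 243 in EBSS evDNA, so some called peaks are missing from the lists. A score per peak, deposited by the authors, equals the whole part of 10 times the −log10 p and was not used further. Folds, p and q are the authors' values for single peaks and were used only to describe, rank or filter peaks within a list. The lists end at a −log10 p of 2.30, the value of 0.005, with no limit on q, so most peaks do not pass q of 0.05. Which control the authors gave to the peak caller is not given in the sources used here. If both immunoprecipitations were called against the same input, part of their overlap may come from it. Coordinates are 1-based, as deposited.

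Peaks with several summits in 1 interval were merged to the strongest summit. The number of fragments at each summit and the local background were recovered by solving the fold, (pileup + 1) / (background + 1), and the Poisson −log10 p together for a whole pileup. In each list, 100% of intervals matched within 0.01. Pileups that come out whole mean that the libraries had not been scaled down. Relative depth was estimated as the lowest background in a list (its 1% quantile) divided by its smallest peak width, taken as the fragment length; this is an estimate from the lists, and read totals are unknown. A library with fewer fragments shows fewer weak peaks, so list lengths and shares of lists depend on depth. Regions over 500 kb from any protein-coding gene, unplaced scaffolds and the mitochondrial genome are called gene-free, and peaks with a recovered background of 10 fragments or more are called high-background.

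Peaks shared 2 lists when at least 1 bp overlapped. The number of overlapping peaks of the first list was set against 1000 random placements of its peaks on their own chromosomes, with peak lengths kept, in a two-sided permutation test; 0.5 was added to both counts in the ratio. Assembly gaps were not left out, since no genome sequence was used. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only; differences of shares have normal 95% intervals. Genes were matched by symbol or synonym to a table of RefSeq genes on GRCh38.p14, the same assembly as hg38; 65.4% to 72.8% of the gene names in a list matched, the rest being mainly names of clones, pseudogenes and noncoding RNAs. A promoter peak lies within 1 kb of a TSS in the authors' annotation. Promoter genes of FOXM1 and LC3 were compared by Fisher's exact test over 20052 protein-coding genes. The 14 gene lists were FOXM1 and G2/M cell cycle genes, MuvB and B-MYB complex, autophagy, lysosome and TFEB targets, vesicle biogenesis, nuclear lamina and envelope, cytosolic DNA sensing, NRF2 targets, amino acid starvation response, housekeeping genes, replication-dependent histone genes, lung epithelial genes, lineage genes of blood and neurons, and long genes at common fragile sites. Each list's count of promoter genes was ranked among 10000 random lists of the same size, matched on gene length in 10 bins, as a description of these libraries.

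Genes were named by a rule: the 10 protein-coding genes with the highest fold at a promoter peak in each list; the 10 with the best worse rank in both FOXM1 and LC3, and in FOXM1, LC3 and an evDNA list; up to 4 members of each gene list with promoter peaks in the most lists; the 5 leading genes of shared and unshared evDNA peaks; FOXM1, MAP1LC3A, MAP1LC3B, MAP1LC3C and CDKN2A; the 3 peaks of highest fold per list by position; and the 5 strongest FOXM1 and LC3 overlaps over 3 kb from a TSS. MAP1LC3B2, ITFG2, CSMD1, RPL13A, TBC1D5, HBB, FOXA2, CTTNBP2, KCNN2, the REXO1L, POTE and ARHGAP42P families, and the genes named only in the closing section, were named after their values were seen. Of the 3 highest control evDNA peaks by position, 1 is not listed, and 1 gene that the rule takes is not reported here. The tests, lists, rule and the alternatives described as planned were fixed before the data were examined. Motif searches at peak summits and placements by annotation class were planned but need a genome sequence or annotation and were not run.

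Alternatives changed the placement, the overlap that counts as shared, the threshold on q, the list length, the regions used and the definition of a promoter. The placement test was run on simulated lists of FOXM1 and LC3 size, with 100 placements per pair. Of 40 unrelated pairs, 1 had p under 0.05, and in 5 of 5 pairs with 100 planted overlaps the test passed, with a mean excess of 96.8. The simulated peaks were scattered at random over each chromosome, as the test itself places them. These runs check the computation and cannot tell whether the p-values hold for real peaks, which are not spread in this way. Of 200 simulated lists of 20 genes, 200 with 4 planted promoter genes reached the top 2.5% and 0 without did. In these runs every gene had the same chance of a promoter peak, whatever its length. They too check only the computation and do not show how often lists with fewer such genes would pass. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.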

Results

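The series profiled DNA bound or carried in A549 cells, an established line from a human lung adenocarcinoma. Chromatin was immunoprecipitated with an antibody against FOXM1, a forkhead transcription factor of the cell cycle, and with an antibody against LC3, a family of ubiquitin-like proteins that are attached to autophagosome membranes. DNA was also sequenced without an antibody from extracellular vesicles (evDNA) of untreated cells and of cells kept for 3 days in EBSS, a salt solution without amino acids or serum. By its title, the series asked whether FOXM1 specifies which chromatin DNA reaches vesicles, so the comparisons are of where the 4 peak lists lie relative to each other. Each group had 1 library. No difference between conditions could therefore be tested against replicate error, and each p-value below describes the lists, not the conditions. The input library of the immunoprecipitations was not analysed here. The lists held 11229 FOXM1 peaks, 7834 LC3 peaks, 29248 control evDNA peaks and 15544 EBSS evDNA peaks, on hg38. After merging peaks with the same interval, 11195, 7801, 28993 and 15402 remained. Relative depth, estimated from the genome background in each list, was 0.479 for FOXM1, 0.762 for LC3 and 1.006 for EBSS evDNA, with control evDNA set at 1. Peaks were shallow: the median pileup was 5 fragments for FOXM1, 8 for LC3, 9 for control evDNA and 8 for EBSS evDNA. Only 221 FOXM1 peaks, 295 LC3 peaks, 3850 control evDNA peaks and 1505 EBSS evDNA peaks had q of at most 0.05.

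The first comparison asked where FOXM1 lay in chromatin. The FOXM1 gene itself held the strongest peaks of the FOXM1 list. The highest, on chromosome 12 from 2858423 to 2859850, had a fold of 182 and lay in the 3' part of FOXM1, which spans 2857680 to 2877174 on the minus strand; the authors' annotation assigned it to the neighbouring gene ITFG2. A second, from 2873789 to 2874682, had a fold of 116, and the peak over the start of the gene, from 2876849 to 2878290, had a fold of 16.4 and was assigned to TULP3. Outside that locus, peaks lay at MAP1LC3B2, an LC3 family gene (chromosome 12, 116575759 to 116576445, fold 74.3), at the promoter of VIM, which encodes the intermediate filament vimentin (chromosome 10, 17226615 to 17228481, fold 62.0), and at the promoter of CDH1, which encodes E-cadherin (chromosome 16, 68735589 to 68737418, fold 13.99). The mitotic kinase genes PLK1 (fold 6.87, −log10 q 9.98) and CDK1 (fold 5.97, −log10 q 5.996), both known as FOXM1 targets, had promoter peaks too. The 10 protein-coding genes with the strongest promoter peak were completed by PGK1 (22.6), CARM1 (15.7), EEF1A1 (8.58) and TRIM21 (6.90). Of the LC3 genes named in advance, MAP1LC3B had 1 FOXM1 peak, in its 3' part (chromosome 16, 87402924 to 87403301, fold 13.0), and MAP1LC3A and MAP1LC3C had none in any list. In all, 17 FOXM1 peaks reached a fold of 10. Of these, 5 overlapped an evDNA peak (29.4%, exact 95% interval 10.3 to 55.96%) and 7 an LC3 peak (41.2%, 18.4 to 67.1%), against 2.70% and 1.32% of the 11178 other FOXM1 peaks. These peaks are not independent places: 3 of the 5 lay in the FOXM1 gene, with TBC1D5 and PGK1 as the others, and the 7 were 2 in the FOXM1 gene and 1 each at MAP1LC3B2, VIM, HBB, PGK1 and FOXA2. Cloned DNA was not excluded as their origin. Intervals of shares here and below are Clopper-Pearson intervals, and those of differences of shares are normal intervals. Both cover counting error only.

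**Figure D1:**
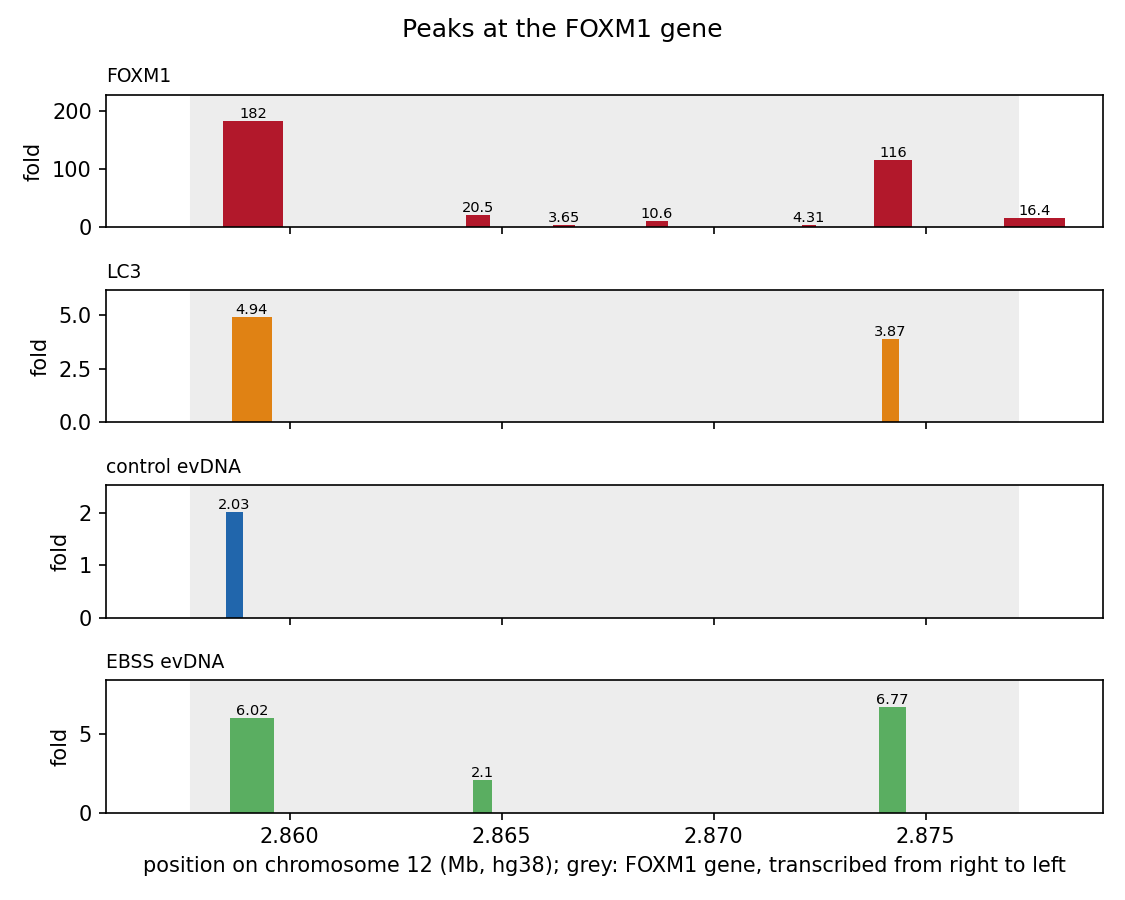
Peaks at the FOXM1 gene in each of the 4 lists. The x axis is the position on chromosome 12 in Mb, bar width is the peak's extent, bar height is the authors' fold with a separate axis per list, and grey marks the gene. The FOXM1 list has folds of 182 and 116 inside the gene and 16.4 at its start, and the 2 inner positions recur in the LC3 and EBSS evDNA lists at folds of 3.87 to 6.77. In control evDNA only the position of the highest peak recurs, at a fold of 2.03 (−log10 q 0.302).

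LC3 peaks lay far more often at promoters than FOXM1 peaks. The median fold was 3.02 for LC3 and 2.89 for FOXM1. Of the LC3 peaks, 28.5% (27.5 to 29.6%) lay within 1 kb of a transcription start site (TSS), against 6.10% (5.67 to 6.56%) of FOXM1 peaks, 9.28% of control evDNA peaks and 9.39% of EBSS evDNA peaks. The highest LC3 fold, 10.0 against 182 for FOXM1, was again at MAP1LC3B2 (chromosome 12, 116575825 to 116576390, in the authors' 5' UTR class), followed by 2 intergenic peaks in or beside the centromere of chromosome 10 (40596303 to 40596644, fold 7.27, and 41564622 to 41564994, fold 6.82). The authors' annotation assigned the peak within MAP1LC3B2 to AC125603.4 in both the LC3 and the FOXM1 list. VIM had the strongest LC3 promoter peak (fold 6.49, −log10 q 6.86). Next came PIAS1, which encodes a SUMO ligase (5.52), RAPGEF4 (5.46), UBN2 (5.45), TESC (5.31), SDC2, which encodes the cell-surface proteoglycan syndecan 2 (5.19), ATP5F1C, a subunit gene of mitochondrial ATP synthase (5.17), FAM181B (5.03), PDE3B (4.93) and MAPK4 (4.93). Promoter peaks were found at 1580 protein-coding genes for LC3 and at 310 for FOXM1, of 20052. Intergenic peaks made up 29.3% of the LC3 list and 43.1% of the FOXM1 list. Shares at promoters were not tested between lists. Among peaks with −log10 q of at least 5, 20.9% of 86 FOXM1 peaks and 15.8% of 19 LC3 peaks lay at promoters, too few LC3 peaks to tell an order. With q of at most 0.05, chosen after the values were seen, LC3 led. The shares were then 41.4% of 295 LC3 peaks (35.7 to 47.2%) and 13.6% of 221 FOXM1 peaks (9.35 to 18.8%).

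**Figure D2:**
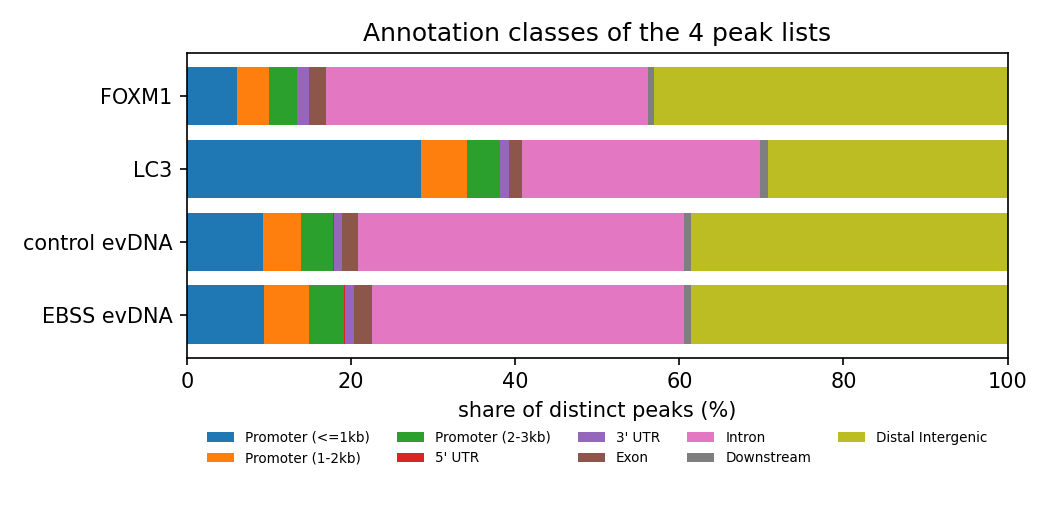
Share of distinct peaks in each class of the authors' annotation, in percent, for the 4 lists. The promoter class within 1 kb of a TSS takes 28.5% of LC3 peaks and between 6.10% and 9.39% of the other lists.

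The next comparison asked whether FOXM1 and LC3 peaks lay at the same places. They met at 155 FOXM1 peaks, 1.38% of that list, where random placement on the same chromosomes gave 25.4 ± 4.92 (SD over 1000 placements). This was 6.01 times the placed number, with a two-sided permutation p of 0.002, the smallest that 1000 placements can give. The strongest shared promoters were those of VIM, FOXM1 and LSAMP, a neuronal adhesion gene (fold 4.33 in FOXM1 and 3.41 in LC3). The strongest shared peaks far from a TSS were MAP1LC3B2, the 2 places at the chromosome 10 centromere (FOXM1 folds 7.77 and 7.70), and places at the centromeres of chromosome 2 (92198875 to 92199429, fold 6.42) and chromosome 5 (47140519 to 47140963, fold 6.68). Of the shared peaks, 36.8% lay in gene-free or high-background regions, against 14.03% of the FOXM1 peaks that were not shared. Counted by gene, 54 protein-coding genes had a promoter peak in both lists, with an odds ratio of 2.52 (two-sided Fisher's exact test, p = 2.9e-08). The odds ratio of FOXM1 was 2.52 with control evDNA and 2.79 with EBSS evDNA, so sharing of promoter genes was not particular to LC3. Only 12 of these 54 genes had promoter peaks that overlapped; POTEG and FAM174B were among them, while at EPHA4, an ephrin receptor gene, ERC2, ADGRV1, PRKAG2 and ATXN2 the peaks of the pair lay apart. The 54 genes were long (median 154.5 kb, against 24.1 kb over all protein-coding genes), and within bins of gene length the odds ratio was 1.73 (permutation p = 0.0016), an alternative chosen after the values were seen. With q of at most 0.05, also chosen then, only 2 genes had a promoter peak in both lists, of 16 in FOXM1 and 94 in LC3. These were VIM and FOXM1, at FOXM1 peaks of fold 10 or more, where cloned DNA was not excluded. Among peaks with q of at most 0.05, also chosen then, 37 of 221 FOXM1 peaks met an LC3 peak, against at most 2 in any placement. Of these 221 peaks, 59.3% were intergenic, against 43.1% of all FOXM1 peaks. That setting placed peaks over whole chromosomes and kept gene-free and high-background regions, so it cannot tell how many of the 37 come from such regions.

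Of the 14 gene lists fixed in advance, 4 had so many members with a FOXM1 promoter peak that they stood in the top 2.5% of random lists of equal size and gene length. For FOXM1 and G2/M cell cycle genes these were 3 of 35 members, FOXM1, PLK1 and CDK1 (percentile 99.2). They were 2 of 20 housekeeping genes, PGK1 and EEF1A1 (98.9), 2 of 17 targets of the antioxidant factor NRF2, GCLC and SLC7A11 (98.0; −log10 q of 0.13 and 0), and 4 of 14 long genes at common fragile sites, CSMD1, DMD, NRXN3 and LSAMP (99.7). The remaining FOXM1 counts were 2 of 16 nuclear lamina and envelope genes (SYNE1, fold 4.04, and TPR, 2.76; percentile 95.8), 1 of 18 lung epithelial genes (CDH1) and 1 of 23 lineage genes of blood and neurons (MS4A1). None of the 10 MuvB and B-MYB genes, 28 autophagy genes, 19 lysosome genes, 24 vesicle biogenesis genes, 13 cytosolic DNA sensing genes, 14 amino acid starvation genes and 12 histone genes had one. Of the LC3 list, housekeeping genes alone reached the top 2.5%, with 4 of 20 members (GAPDH, PGK1, SDHA and RPL13A; percentile 98.1). The autophagy list had 1 LC3 member of 28, RB1CC1, a gene of the autophagy initiation complex (fold 3.52), and 1 member in control evDNA, UVRAG. Lysosome genes had LC3 peaks at CTSB and GAA and EBSS evDNA peaks at CTSD and ATP6V0D1. RAB27A (LC3) and RAB27B (control evDNA) of the vesicle list, LEMD2 and TMPO (LC3) of the envelope list, IFI16 (LC3 and control evDNA) of the DNA sensing list, TALDO1 (LC3) and ME1 (control evDNA) of the NRF2 list, EPCAM (LC3) of the lung list and CD8A (LC3), SNAP25 and MBP (control evDNA) of the lineage list had peaks below a fold of 4.2. With all peaks, no list reached the top 2.5% in either evDNA list, where BUB1 and FOXM1 stood among the 3 cell cycle genes of EBSS evDNA. With 56 combinations of gene list and peak list, at most 1.4 would do so by chance on average. Without the genes at FOXM1 peaks of fold 10 or more, the cell cycle list kept PLK1 and CDK1 at percentile 93.3, and the housekeeping list EEF1A1 at 87.0 for FOXM1 and 3 of 19 genes at 92.6 for LC3, all outside the top 2.5%. With promoters up to 3 kb, the FOXM1 percentiles were 94.65 for cell cycle, 95.95 for housekeeping and 91.97 for NRF2 genes, also outside. With −log10 q of at least 5, no NRF2 or fragile site gene and no LC3 housekeeping gene kept a promoter peak, while 2 EBSS evDNA counts of 1 gene each, FOXM1 (98.67) and PGK1 (98.43), came into the top 2.5%. The length bins are coarse for genes as long as those at fragile sites, all 14 of which had some FOXM1 peak.

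**Figure D3:**
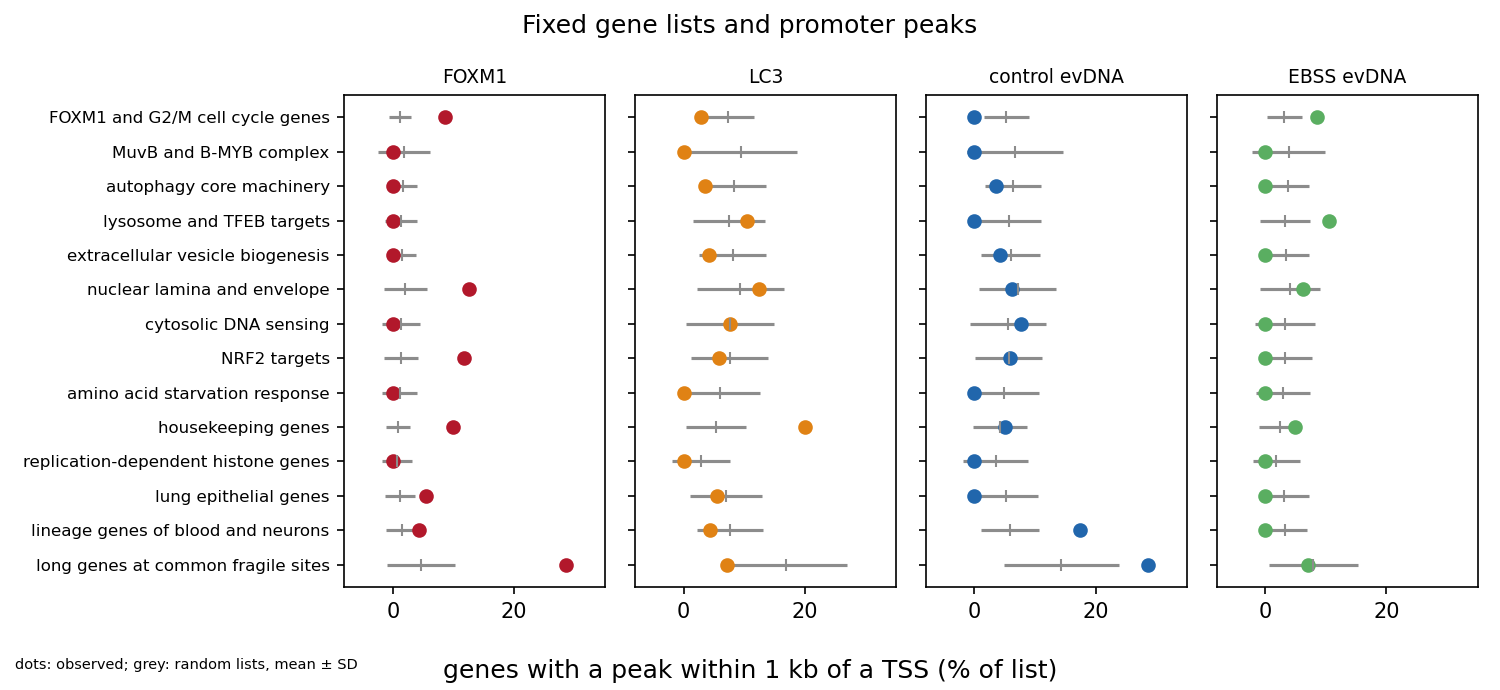
Share of each fixed gene list with a peak within 1 kb of a TSS, in percent, in the 4 peak lists. Coloured dots are the observed shares and grey marks are the mean and SD over 10000 random lists matched on size and gene length; the FOXM1 dots of the cell cycle, NRF2, housekeeping and fragile site lists and the LC3 dot of the housekeeping list lie in the top 2.5%.

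A further comparison asked whether vesicle DNA was enriched at places bound by FOXM1 or LC3. Both FOXM1 and LC3 peaks met evDNA peaks more often than placed peaks did. FOXM1 met control evDNA at 229 peaks, 2.53 times the placed number, and EBSS evDNA at 153, 3.30 times. LC3 met control evDNA at 263 peaks, 4.03 times, and EBSS evDNA at 147, 4.34 times; each of the 4 had p = 0.002 by permutation, the smallest possible. These were small parts of the lists: 10769 of the 11195 FOXM1 peaks met no peak of the other 3 lists. Of the FOXM1 peaks shared with control and EBSS evDNA, 33.2% and 44.4% lay in gene-free or high-background regions, against 13.95% and 13.93% of those not shared. For LC3 the shares were 17.5% and 25.85%, against 3.94% and 3.985%. Without high-background peaks, chosen after the values were seen, the ratios were 2.08 and 2.48 for FOXM1 and 3.69 and 3.68 for LC3. Places in FOXM1, LC3 and an evDNA list numbered 36, of which 18 lay in gene-free or high-background regions. Of the other 18, 8 were nearest to copies of the GAGE, REXO1L, TAF11L, POTE and ARHGAP42P families, where reads cannot be placed with certainty. The 18 also held 2 places in the FOXM1 gene, and the PGK1 promoter (chromosome X, 78103668 to 78104483), whose folds were 22.6 in FOXM1, 3.03 in LC3 and 8.84 in EBSS evDNA. Cloned DNA was not excluded at the FOXM1 and PGK1 places. At the rest of the 18 the FOXM1 −log10 q was 0 to 0.675, apart from 2.27 at a place on chromosome 8 (7766560 to 7767302). The recovered FOXM1 background at that place was 8.61 fragments, just under the bound of 10 and far above the list's median of 1.08. By promoter genes, FOXM1, LC3 and control evDNA shared 11 genes and FOXM1, LC3 and EBSS evDNA shared 7. These included LSAMP, ERC2, NBPF12, ESRRG, LRRC9 and CD44, the hyaluronan receptor gene, with control evDNA, and PDE4DIP and TMTC1 with EBSS evDNA, at folds of 2.57 to 4.33. The promoter peaks mostly did not coincide with control evDNA: the vesicle peak overlapped a FOXM1 or LC3 promoter peak at 3 of the 11 genes (CTTNBP2, KCNN2 and TAF11L6). With EBSS evDNA it did so at 5 of the 7 (FOXM1, PGK1, POTEG, TAF11L6 and TMTC1). The share of evDNA peaks with a FOXM1 peak was 0.797% (0.698 to 0.906%) in control and 1.00% (0.849 to 1.17%) in EBSS, a difference of 0.203 percentage points (0.0156 to 0.391). With at least 50% of the shorter peak shared it was 0.254 points (0.085 to 0.4235). Without gene-free regions, chosen after the values were seen, it was 0.0809 points (−0.0913 to 0.253), and at equal list lengths −0.0519 points (−0.277 to 0.173), so the direction did not hold there. The share with an LC3 peak was 0.900% in control and 0.961% in EBSS, and the interval of the difference, −0.128 to 0.249 points, included 0. At equal list lengths the LC3 difference turned too, to −0.0714 points (−0.293 to 0.150).

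**Figure D4:**
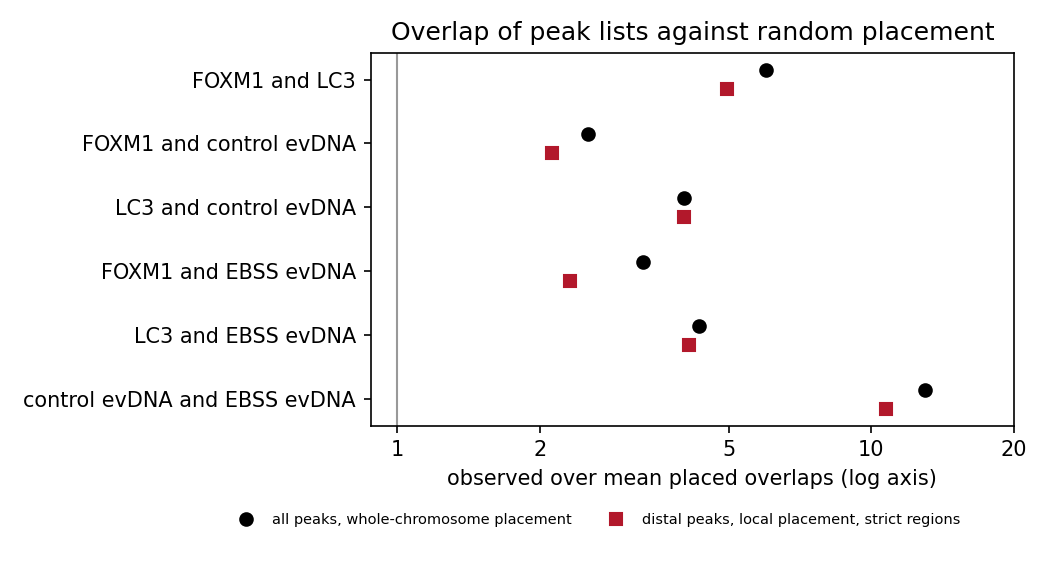
Observed overlaps divided by the mean of 1000 random placements for the 6 pairs of lists, on a log axis. Black dots use all peaks placed anywhere on their chromosome and red squares use distal peaks placed within 1 Mb of their position without gene-free and high-background regions; all 12 values lie above 1, from 2.13 to 13.0.

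Control and EBSS evDNA shared 1875 of the control peaks, 13.0 times the placed number (p = 0.002 by permutation, the smallest possible), and many of their strongest peaks lay in or beside centromeres or in arrays of gene copies. The shared peaks of highest fold assigned to protein-coding genes were a place on chromosome 5 at the centromere (49630720 to 49631199, nearest gene EMB, fold 21.2 in control and 23.3 in EBSS), the DUX4 array on chromosome 4 (14.9 and 15.6), a place near DEFB115 on chromosome 20 (16.8 and 14.6), the cancer-testis gene GAGE2A (11.8 and 10.9) and USP17L18 (10.1 and 10.5). By position, the highest folds were 29.9 and 28.7 in EBSS evDNA on chromosome 17 (25919990 to 25920442 and 26594502 to 26595132) and 27.1 on chromosome 6 (59163011 to 59163474), and 24.9 and 24.0 in control evDNA on chromosome 17 (26594675 to 26595123 and 23016135 to 23016665). GAGE, USP17L and TAF11L genes, copies of which follow each other in arrays, took 7 of the 10 strongest promoter peaks in control evDNA and 6 of the 10 in EBSS evDNA. Reads from such copies cannot be placed with certainty. Mucin genes MUC3A (control, 5.51) and MUC6 (EBSS, 5.34) and the neuronal gene MYT1L (EBSS, 5.95) were also among them. Peaks in EBSS evDNA with no control counterpart were led by the PGK1 promoter (8.84, −log10 q 19.99) and the inner FOXM1 peak (chromosome 12, 2873898 to 2874550, fold 6.77, −log10 q 23.02), then MUC12 (5.52), PRR20B (5.24) and ARHGEF5 (4.89). The PGK1 and FOXM1 places were also FOXM1 peaks of fold 10 or more, where cloned DNA was not excluded. Strong peaks in control evDNA with no EBSS counterpart included OR2A1 (5.22), DHX32 (5.19), RICTOR, a subunit gene of the mTORC2 kinase complex (5.11), and NAIP (5.02). Whether reads at the unshared peaks of either list could also come from other gene copies was not checked. Chromosome 5 carried RICTOR and NAIP. Of the peaks on chromosomes 1 to 22 and X, it held 15.2% in control evDNA and 11.9% in EBSS evDNA, at 5.99% of their length. It also held 9.68% of FOXM1 peaks and 8.455% of LC3 peaks, so an excess there was not particular to vesicle DNA. CDKN2A, a tumour suppressor gene that A549 cells are known to lack, held 1 control evDNA peak (chromosome 9, 21975448 to 21975732, fold 3.07, −log10 q 0.716) and no peak in the other lists. The 1 Mb window around it held 5 FOXM1, 3 LC3, 2 control evDNA and 5 EBSS evDNA peaks. The chromosome 9 medians per window were 3, 2, 6 and 4, and 22, 37, 22 and 26 of its 139 windows held no peak. The window is far wider than the gene and peaks are sparse, so these counts cannot show whether the gene is lost. Which of these differences come from EBSS cannot be told from 1 library per condition.

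**Figure D5:**
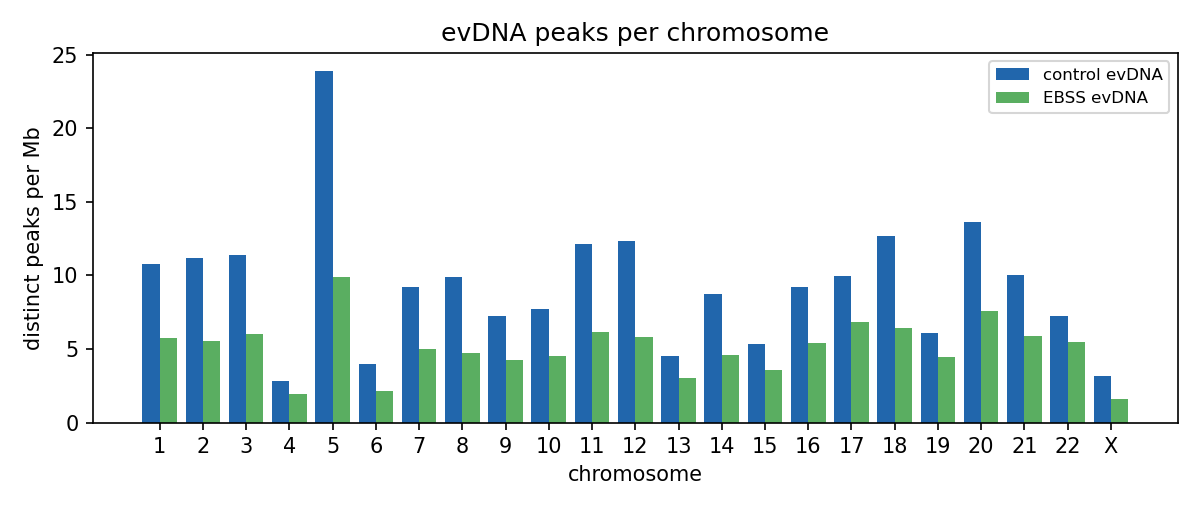
Distinct evDNA peaks per Mb on chromosomes 1 to 22 and X, for control and EBSS vesicles. Chromosome 5 stands highest in control evDNA, at 23.9 peaks per Mb, with 9.88 in EBSS evDNA.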

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

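All 6 overlaps of peak lists kept their direction and a permutation p of 0.002 under each of 13 alternatives, 78 comparisons in all, 4 of the 13 chosen after seeing the data. Where at least 5 overlaps were placed on average, the ratio ranged from 3.31 to 8.11 for FOXM1 and LC3, 1.69 to 3.615 for FOXM1 and control evDNA, 1.93 to 4.70 for FOXM1 and EBSS evDNA, 2.38 to 5.94 for LC3 and control evDNA, 2.62 to 5.99 for LC3 and EBSS evDNA and 6.57 to 36.1 for the evDNA lists. In the other 10 comparisons, all with a bound on q, the 0.5 added to both counts weighs on the ratio, and each observed count lay above every placement. The EBSS minus control difference in the share of evDNA peaks with a FOXM1 peak turned to −0.0519 points at equal list lengths, and that for LC3 from 0.0607 to −0.0714; the control list is longer, and its strongest peaks met FOXM1 and LC3 more often. With −log10 q of at least 5 it was 2.38 points (−1.93 to 6.69) for FOXM1 and 1.40 (−1.97 to 4.775) for LC3, on 470 and 424 peaks. With at least 50% of the shorter peak shared it was 0.254 points for FOXM1, and without gene-free regions, chosen after seeing the data, 0.0809 (−0.0913 to 0.253). Promoter shares moved with the definition of the peaks, and the cause was not tested. Counting a promoter up to 3 kb gave 13.4% for FOXM1, 38.1% for LC3, 17.8% for control evDNA and 19.1% for EBSS evDNA. With −log10 q of at least 5 they were 20.9%, 15.8% (19 LC3 peaks), 11.5% and 11.1%, with too few LC3 peaks to tell whether LC3 still led. With q of at most 0.05, chosen after seeing the data, they were 13.6%, 41.4%, 9.25% and 9.97%, where the control evDNA share hardly moved. Without gene-free regions, also chosen then, they were 6.71%, 29.7%, 9.86% and 10.1%. Of the 56 gene list combinations, 2 reached the top 2.5% with promoters up to 3 kb (fragile site genes in FOXM1 and housekeeping genes in LC3), 1 with any annotated peak (fragile site genes in FOXM1), 5 with −log10 q of at least 5 (cell cycle, housekeeping and lung epithelial genes in FOXM1, and 2 lists in EBSS evDNA), and 2 (NRF2 and fragile site genes in FOXM1) without the genes at FOXM1 peaks of fold 10 or more (chosen after seeing the data), against 5. The odds ratio for FOXM1 and LC3 promoter genes turned to 0.212 when the background was the genes with a promoter peak in any list; that background leaves out the 16685 genes with no promoter peak and keeps 1531 with neither, which by itself pushes the odds ratio below 1: 1000 pairs of random gene sets of the same sizes had a median of 0.0902 and at most 0.1685 (also run after seeing the data). The 3 motif alternatives were not run. No paired analysis was possible because each group has 1 library. Depth limits the FOXM1 list most: its median pileup of 5 fragments is 1 above the lowest listed, 4.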

Other observations

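No theme was tested among the genes under the strongest FOXM1 peaks. Besides FOXM1, MAP1LC3B2 and VIM, the 17 peaks of fold 10 or more lay at HBB, a beta-globin gene (chromosome 11, 5224759 to 5226324, fold 30.2), an intron of TBC1D5 (chromosome 3, 17401795 to 17402425, fold 24.6), PGK1, CARM1, the growth hormone gene GH1 (chromosome 17, 63916560 to 63917440, fold 14.4), CDH1, MAP1LC3B, PHF2 and FOXA2 (chromosome 20, 22581861 to 22583156, fold 10.3). HBB (2.85) and FOXA2 (3.54) recurred in LC3 and TBC1D5 (3.84) in EBSS evDNA. PHF2, a histone demethylase gene, had peaks in exons 12, 18 and 21 of 22 at folds of 5.82, 6.01 and 10.9. In the mitochondrial genome, 1 FOXM1 interval covered 16438 bp, 4 control evDNA intervals 7506 bp and 3 EBSS evDNA intervals 7835 bp. No LC3 peak lay there.

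The tests below were chosen after the results were seen, except 2 whose outcome was not known when they were written down: the neighbouring peaks on chromosome 12 and the ratio per chromosome.

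Extra copies of the region around the FOXM1 gene were predicted to give further peaks of fold 5 or more nearby. Within 1 Mb to each side there were 0, and the highest of 2 other peaks was at 3.85. Strong folds were thus limited to the gene. This cannot decide on extra copies, since the fold is over the local background, which extra copies would raise too. Binding of FOXM1 protein at its own promoter would put the highest peak at a start of the gene. The highest peak was 11.1 times the fold of the peak over the gene's start. It was only 1.575 times that of the second peak, which the authors' annotation puts at another FOXM1 start. Their pileups were 499 and 380 fragments, a ratio of 1.31 with an interval of 1.15 to 1.505. The annotation also puts inner peaks of fold 20.5 and 10.55 at FOXM1 starts, so lying at a start separates little in this gene. Binding at the gene's own promoter stays open.

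Another candidate explanation of the strong peaks is DNA of cloned genes in the libraries, since HBB, GH1, PGK1 and EEF1A1 sequences are common vector parts and cloned genes lack introns. Of the 7 genes with a FOXM1 peak of −log10 q of at least 5 off promoters, 42.86% had it in an exon or UTR, against 11.7% of 3115 other genes (Fisher's exact test, two-sided, p = 0.040). These are MAP1LC3B2, CARM1 and PHF2 (AC125603.4, CARM1 and MIR548AU in the authors' annotation), whose peaks of fold 10 or more prompted the idea. Without genes that have such a peak, 0 of 3 remained, so cloned DNA stays open. The test also could not take in the FOXM1 gene, VIM, HBB, PGK1 or GH1. The authors' annotation puts their peaks of fold 10 or more in promoter classes, up to 3 kb from a TSS. Counted by peak the share was 55.6% of 9, but 3 of those 5 exon or UTR peaks lie in PHF2.

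The FOXM1 and LC3 overlap was weighed against explanations of its whole size. Repeated sequence in gene-free and high-background regions is argued against, since among distal peaks, placed locally and without gene-free and high-background regions, 61 overlaps stood against at most 25 in any placement, a ratio of 4.95. Repeated sequence elsewhere was not removed, since no repeat annotation was used, and stays open. Regional copy number is argued against by local placement alone, with a ratio of 5.77. Places that draw peaks in every kind of library stay open. In that strict setting the lower 95% counting bound of the FOXM1 and LC3 ratio was 3.92, above the upper bounds of FOXM1 with control (2.56) and EBSS evDNA (3.02). It was below those of LC3 with control (4.88, at a ratio of 4.03) and EBSS evDNA (5.45, at 4.12), and ratios also depend on list length. A shared input or shared handling of the 2 immunoprecipitations, and joint binding of FOXM1 and LC3, were not tested and stay open too.

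Control evDNA had 1.88 times as many distinct peaks as EBSS evDNA. Deeper sequencing is argued against by the background per bp of fragment, whose ratio was 0.995. Extra peaks on a few chromosomes are argued against by a median ratio of 1.83 over 23 chromosomes, with each above 1, from 1.32 on chromosome 22 to 2.42 on chromosome 5. Peaks near the calling threshold are argued against as the whole cause: with −log10 p of at least 4 in both lists, against 2.30 at the threshold, the ratio was 2.20 (2.12 to 2.28). It was 1.78 (1.64 to 1.93) at 6, 1.19 (1.06 to 1.35) at 8 and 1.09 (0.9499 to 1.257) at 10, where the interval includes 1, so the excess lay mostly among weaker peaks. The bound on p replaced bounds on q, which shift with the length of a list and gave 2.56 at q of at most 0.05 and 1.11 at −log10 q of at least 5. An effect of EBSS on vesicle DNA and a chance difference between 2 vesicle preparations both stay open, since each condition has 1 library.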
